A study of Homo sapiens with 2 samples.

How the data were processed

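Total RNA from HEK 293 cells, an established human embryonic kidney line, had been labelled with Cy3 from 50 ng by a low-input amplification kit and hybridised to Agilent SurePrint G3 Human gene expression arrays, per the labels' protocols. The labels' extraction text also mentions HaCaT cells, a keratinocyte line not analysed here. There were 2 arrays, 1 of untreated cells (0 µM) and 1 of cells given 1.63 µM cetuximab, with an exposure of 24 h per the series' design text. Groups were taken from the sample titles.

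The deposited scanner files give fluorescence intensity per spot. Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.1.1. The headers record no subtraction of local background, spatial and multiplicative detrending, and replacement of very dim spots by surrogate values. No scaling between arrays is recorded in them. Probe positions in the files carry the hg19 build, and the probes are 60 bases long. The authors' table for the whole series was left out because its 4 columns have names that match neither sample's labels. How the authors normalized that table is not given in the sources used here.

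From the deposited intensity values, the processed signal was taken as log2, and spots marked as non-uniform or population outliers were left out. Spots of the same probe were averaged. Each array's 75th percentile over its 50599 non-control probes was subtracted. A probe counted as measured when most of its spots were marked well above background. Each gene took the brightest of its probes that were measured on both arrays, and differences are cetuximab minus control on the log2 scale. A gene measured on 1 array only has a bound, the signal on that array over the higher of the other array's lowest well-above-background signal and the probe's own signal there. A gene was counted as higher or lower when it differed at least 2-fold. Of 29181 probes with a RefSeq accession, 28174 (96.5%) matched a current symbol in a RefSeq gene table of assembly GRCh38.p14, used for names only. The array's own gene names are printed, with the current symbol where it differs.

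Each group held 1 array, so no test between groups was run and no p-value is given. The number of arrays limits the precision. Technical spread came from 665 measured probes with at least 5 spots on each array. It covers the array and not the culture, the RNA preparation or the labelling. The median SD between spots of the same probe was 0.06 log2 in the control and 0.07 with cetuximab. The SD of a difference between single spots ran from 0.37 in the dimmest 10% of measured probes to 0.07 in the brightest 10%.

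Before the data were examined, the rule for named genes, 40 gene lists and the alternatives below were fixed. Named genes were the 10 largest positive and the 10 largest negative differences among settled symbols in the brighter part of the measured genes (mean signal at or above their median). Unsettled names, such as clone, LOC or antisense names, were passed over. Also named were the 3 largest bounds in each direction, EGFR and its 3 family members, and the 2 members of each list with the largest absolute difference. Genes outside that rule are said to be chosen after their values were seen. Each list's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean signal. That percentile describes these arrays and is not a test across samples. Members were also counted when they lay outside the middle 95% of genes in their signal bin, a count chosen after the data were seen.

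The alternatives fixed at that point were normexp background correction with an offset of 50 in limma 3.58.1 (R 4.3.3), scaling on the median, scaling on the 75th percentile of measured probes, quantile normalization, loess on mean signal (span 0.3), no scaling, no filter on dim probes, the brighter genes alone, the mean of a gene's probes, outlier spots kept, size rules of 1.5-fold and 3-fold, and random lists without matching. Added after seeing the data were loess on mean signal and probe GC content, scaling on the spike-in controls, and random lists matched on signal and GC (10 and 5 bins) or limited to settled symbols. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures matplotlib 3.10.9.

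The steps were tested on simulated data made from the control array's 17657 measured genes with the measured spot noise. All 50 genes raised 3-fold and all 50 lowered 3-fold were called, against 0 of 50 raised 1.5-fold and 3 of 50 lowered 1.5-fold. Among 17457 simulated genes without a change, 14 passed the 2-fold rule. Their differences had an SD of 0.18, against 0.30 in the data. Only spot noise was simulated, so 14 is no false-positive level for the real comparison. Of 200 unchanged lists of 25 genes, 8 lay outside the middle 95% of random lists, and all 100 lists shifted by 0.2 log2 lay above it. These lists were randomly drawn genes, so they do not show how often lists of related genes fall outside. Since the simulated differences spread less than the data's, the 100 of 100 is no detection rate for the real lists, least of all small or dim ones.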

Results

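Gene expression was measured in HEK 293 cells, an established human embryonic kidney line, without drug and after 24 h with 1.63 µM cetuximab, a therapeutic antibody that binds the epidermal growth factor receptor (EGFR). Each group held 1 array, so the differences below have no replicate check. Of 50599 probes, 25017 (49.4%) were well above background in the control and 23957 (47.3%) with cetuximab, and 0 spots were saturated. The 75th percentile of the signal was 232 intensity units in the control and 163 with cetuximab, 1.43-fold lower. The 6 E1A spike-in controls that were well above background differed by 0.01 log2 on average (SD 0.02) before scaling, while the median gene differed by -0.55, 1.46-fold lower. All values below are relative to each array's own 75th percentile. Unscaled, that percentile differed by -0.51 log2, a shift that the scaling took out of every difference. Each list median given later as higher is smaller in size than this shift. Without scaling or with spike-in scaling those medians therefore lie below 0. Without scaling, the same holds for any gene whose positive difference given below is smaller in size than that shift.

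The comparison asked how expression differs in HEK 293 cells exposed to cetuximab, under a study title that speaks of reactions to the drug. Interferon-stimulated genes were higher with cetuximab, among them IFI44L (2.09 log2, 4.25-fold), IFI44 (1.67 log2, 3.18-fold) and ISG15, a ubiquitin-like protein made in the antiviral response (1.12 log2, 2.18-fold). IFI44L and IFI44 were dim, with control signals of 20.4 and 21.6 intensity units from 1 spot each. The lowest control signal marked well above background was 15.4. The technical SDs of their differences were 0.32 and 0.37 log2. With normexp, which compresses dim genes, IFI44L stood at 0.99, IFI44 at 0.80 and ISG15 at 0.98, all under 2-fold. Targets of p53 were higher by smaller amounts, with a median relative to all genes of 0.21 that fell to 0.0075 without a filter on dim probes. Genes of the integrated stress response, which acts through ATF4 on amino acid synthesis and transport, were lower. Genes that report output of the ERK pathway downstream of growth factor receptors were lower too, with a median relative to all genes of -0.14. Their place outside the random range was lost after loess on mean signal (percentile 5.31), at a relative median of -0.11. The relative median was -0.15 after loess on signal and GC (percentile 1.34) but -0.023 with normexp. Most genes differed little, with 16766 of 17657 within 1.5-fold.

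In all, 88 genes were at least 2-fold higher with cetuximab and 22 at least 2-fold lower, most of them dim. Among the 8829 brighter genes, 3 were higher and 1 lower. The 88 and 22 put 80% of these genes on the higher side. That share was 37.0% with median scaling, 68.4% with quantile normalization, 66.0% after loess on mean signal and 91.7% with normexp. It was 4.47% without scaling, 4.05% with spike-in scaling and 67.3% after loess on signal and GC. The SD of all differences was 0.30 log2. For 4187 genes with a second measured probe, the differences of the pair correlated with r = 0.42 across genes, which are not independent replicates.

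**Figure D1:**
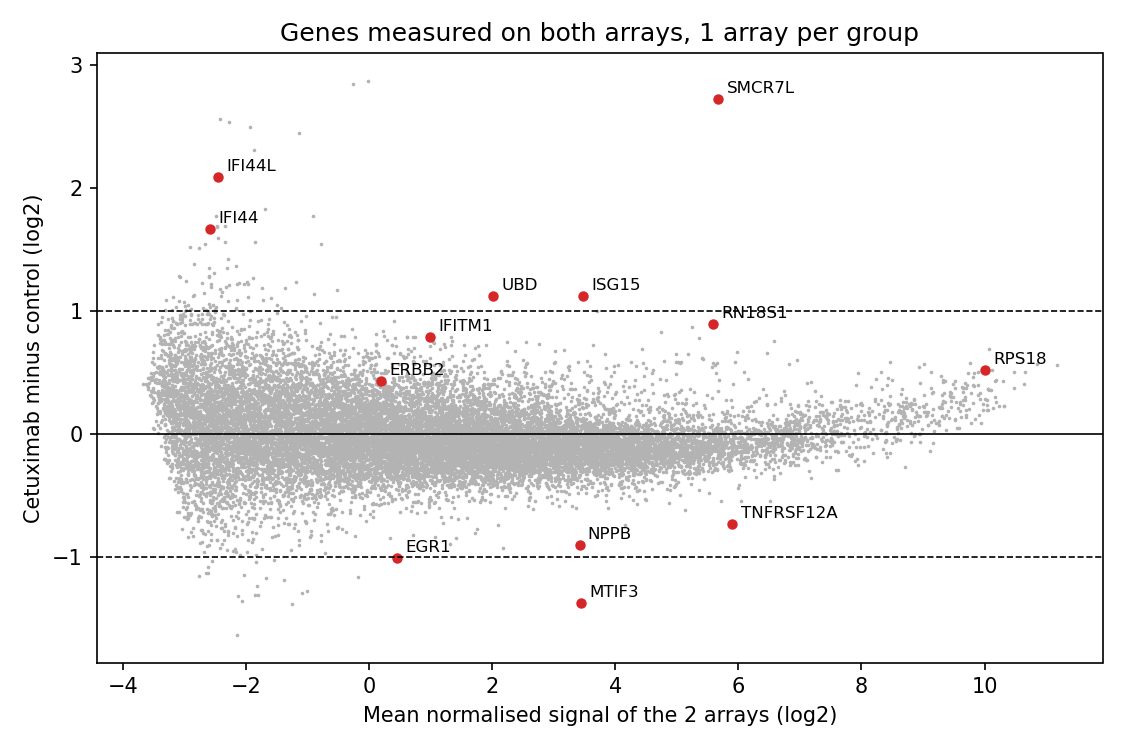
Log2 difference (cetuximab minus control) against the mean normalised log2 signal of both arrays for the 17657 measured genes, each point a gene measured by 1 array per group, with dashed lines at 2-fold and named genes in red. Spread is widest among dim genes, and RPS18 (0.52) is among the brightest genes.

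Among the brighter genes, the largest positive difference was that of SMCR7L, now MIEF1, a regulator of mitochondrial fission (2.72 log2, probe at chromosome 22, 39910169 to 39910228, hg19). Its other 2 probes stood at -0.42 and -0.35, so the gene's probes disagreed, and their mean gave 0.65. ISG15 (chromosome 1, 949567 to 949626) and UBD, a cytokine-induced ubiquitin-like protein (1.12 log2, chromosome 6, 29523477 to 29523536), followed. Each was at least 2-fold higher in 8 of 12 other settings, with lows of 0.60 for both under spike-in scaling. Ribosomal RNA probes were also higher, with RN5-8S1 (now RNA5-8SN5) at 1.0 and RN18S1 (now RNA18SN5) at 0.89. IFITM1, an interferon-induced membrane protein that restricts viral entry, stood at 0.79 with a second probe at 0.96, and CCDC88B at 0.79 with a second probe at 1.20. NFKBIL1 stood at 0.88, but its second probe at 0.05. FOXP4, a forkhead transcription factor, was at 0.78 with a second probe at 0.39, and DYTN was at 0.75.

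MTIF3, a mitochondrial translation initiation factor, had the largest negative difference among brighter genes (-1.37 log2, chromosome 13, 28009958 to 28010017). NPPB, which encodes B-type natriuretic peptide, was at -0.90 with a second probe at -0.93 (chromosome 1, 11917629 to 11917688). TNFRSF12A, the receptor of the cytokine TWEAK, was at -0.73, and BCAT1, an aminotransferase of branched-chain amino acids, at -0.74 with a second probe at -0.42. ORAI3, a subunit of calcium channels, was at -0.84 (SE 0.14 between 10 spots). JAKMIP3 was at -0.92, SULT6B1, a sulfotransferase, at -0.82 and LGI4 at -0.80. NOMO1 was at -0.74 with a second probe at -0.59. MKL2, a coactivator of serum response factor, was at -0.77, although its second probe stood at 0.03.

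Of 28 interferon-stimulated genes measured, 23 were above 0 and 4 were at least 2-fold higher, with a list median of 0.26 that lay above all 10000 random lists. Outside the rule for named genes, the next genes were chosen after their values were seen. IRF9, a subunit of the transcription factor that answers type I interferon, was at 1.14 and BST2 at 0.95. RSAD2, an antiviral enzyme, was well above background with cetuximab only, at least 2.45-fold higher, and OAS1 at least 1.36-fold. The bound of OAS1 (0.44 log2) is smaller in size than the unscaled shift of the 75th percentile (-0.51). The list was not uniform, since USP18 stood at -0.21 and IFIT5 at -0.20. Of 20 MHC class I and antigen presentation genes, 13 were above 0 (median 0.07, percentile 98.6), with the immunoproteasome subunit PSMB8 at 0.57 and the peptide transporter TAP2 at -0.51. The median of this list relative to all genes turned to -0.049 with normexp and -0.078 without a filter on dim probes. Inflammatory cytokines and NF-kB targets had a median of 0.16 (percentile 98.4, 17 of 25 above 0), with TNFAIP2 at 0.69 and the cytokine IL11 at -0.72, and its percentile was 94.6 after loess on mean signal. Its median relative to all genes was 0.20, and 0.011 without a filter on dim probes. Immune cell markers had a median of 0.25 over 10 measured genes (percentile 96.4), with CD3D at 0.44 and FCGR2A at 0.74. Before scaling, CD3D had 74.1 intensity units in the control and 70.7 with cetuximab. FCGR2A was dim, with 22.8 and 26.8 units and a technical SD of 0.37. Another FCGR2A probe, well above background in the control only, stood at -0.08. This list lay outside the middle 95% with matching also on GC (percentile 97.8) and without matching (99.4).

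**Figure D2:**
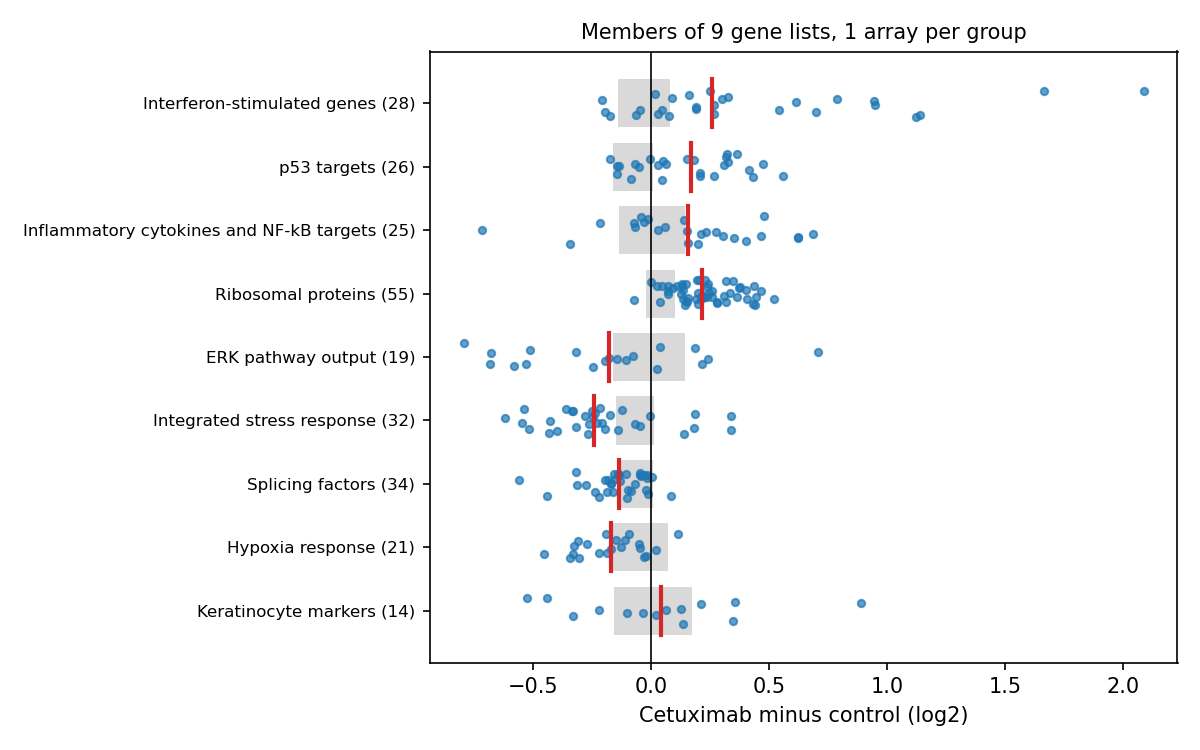
Log2 difference (cetuximab minus control) of each measured member (points, number in brackets) of 9 gene lists with 1 array per group, the list median (red line) and the middle 95% of medians of random lists of like signal (grey band). Interferon-stimulated genes (median 0.26) and p53 targets (0.17) lie above their bands, the integrated stress response (-0.24) below, and keratinocyte markers (0.04) inside.

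EGFR, the target of cetuximab, was near background. Of its 3 probes, 1 was well above background in the control only and another with cetuximab only, so none passed on both arrays and no difference is given. ERBB2, its close relative, was at 0.43 (SE 0.03 between 10 spots), ERBB3 at 0.07 and ERBB4 at -0.12. Before scaling, ERBB2 had 227 intensity units in the control and 215 with cetuximab. The ERBB2 difference ran from -0.09 to 0.51 over 12 settings, so its direction turned with the scaling. The 10 measured EGF receptors and ligands had a median of -0.04, with NRG1, a ligand of ERBB3 and ERBB4, at -0.34. Of 19 ERK pathway output genes, 13 were below 0 (median -0.18, percentile 1.5) and 4 lay below the middle 95% of genes of like signal. The transcription factor ETV1 was at -0.79 and the cytokine LIF at 0.71. With normexp the dim gene ETV1 stood at -0.12. Chosen after its value was seen, DUSP6, a phosphatase that limits ERK, was at -0.68. Immediate early genes went both ways, with EGR1 at -1.01 (at least 2-fold lower in 6 of 11 other settings) and FOS at -0.62 but a list median of 0.09 over 19 genes (percentile 97.8). That median relative to all genes turned to -0.033 without a filter on dim probes, and the percentile was 87.2 after loess on mean signal.

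Of 32 integrated stress response genes, 27 were below 0 (median -0.24), and all 10000 random lists had a higher median. PSAT1, an enzyme of serine synthesis, was at -0.62 and ASNS, asparagine synthetase, at -0.54. Of 26 p53 targets, 18 were above 0 (median 0.17), above all 10000 random lists, with the DNA damage sensor XPC at 0.56 and TP53I3 at 0.48, although none reached 2-fold. The p53 median relative to all genes was 0.21, and 0.0075 without a filter on dim probes. The second probes of 11 p53 targets stood at percentile 96.5 of random sets of second probes. Hypoxia response genes were below 0 in 19 of 21 cases (median -0.17, percentile 1.92), among them the oxygen sensor EGLN1 at -0.45 and MXI1 at -0.34, although another MXI1 probe stood at 0.24. Glycolysis genes had a median of -0.12 (percentile 1.97, 14 of 18 below 0), with PFKP, a phosphofructokinase, at -0.41 and ALDOC at 0.39. With random lists matched also on probe GC content, hypoxia stood at 3.05 and glycolysis at 3.63, inside the middle 95%. After loess on signal and GC they stood at 1.08 and 2.09, outside it. After loess on mean signal alone hypoxia stood at 0.12 and glycolysis at 3.62.

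Ribosomal protein genes were above 0 in 54 of 55 cases (median 0.22), above all 10000 random lists, led by RPS18 at 0.52 and RPL19 at 0.47. The random lists centred on 0.03, but 18 other genes with settled symbols between the list's signal quartiles had a median of 0.32. The signal bins thus did not match this list's brightness, which limits that comparison. The list's median relative to all genes was -0.016 with quantile normalization, so the direction turned with the scaling. Splicing factors were below 0 in 32 of 34 cases (median -0.14, percentile 1.18), with SRSF6 at -0.56 (another of its probes at 0.19) and SRSF5 at -0.44, and their percentile was 3.46 after loess on mean signal. Proteasome genes were below 0 in 27 of 31 cases (median -0.11, percentile 1.1), with PSMD12 at -0.31 and PSMD11 at -0.29, and their percentile was 5.09 with matching on GC. Second probes lay inside the middle 95% of random sets for splicing factors (19 genes, percentile 39.9), proteasome (8 genes, 59.5) and hypoxia (7 genes, 41.1). In all, 12 of 40 lists lay outside the middle 95% of random lists, 6 above and 6 below. Lists of randomly drawn genes would give 2. Members of the fixed lists may vary together between any 2 cultures, so 2 is no chance level for them.

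The other 28 lists lay inside that range. G2 and mitosis genes had a median of -0.12 over 40 measured genes (percentile 17.2), with CCNA2, cyclin A2, at -0.56 (SE 0.02 between 10 spots) and the checkpoint kinase TTK at -0.45. S phase and replication genes stood at -0.05 over 36, apoptosis regulators at -0.07 over 35 and replication-dependent histones at -0.08 over 52. Of the stress programmes, the unfolded protein response stood at -0.03 over 23 genes, heat shock at -0.12 over 22, NRF2 and oxidative stress at 0.01 over 27, autophagy and lysosome at -0.03 over 29, and metallothioneins and zinc transport at 0.03 over 13. Cholesterol synthesis and uptake stood at -0.08 over 24, fatty acid synthesis at -0.10 over 16, the nuclear-encoded respiratory chain at -0.05 over 43 and drug and xenobiotic metabolism at -0.02 over 11. FOXO targets stood at -0.03 over 19, other receptor tyrosine kinases at -0.06 over 17, TGF-beta and BMP targets at -0.08 over 21, Wnt targets at 0.05 over 13, Notch targets at 0.06 over 12 and the circadian clock at -0.16 over 11. Magnesium and tubular ion transport, a set chosen because kidney magnesium handling depends on EGF, stood at -0.03 over 18, with PVALB at 0.57 and FXYD2 at 0.56. Before scaling, PVALB had 59.1 intensity units in the control and 61.5 with cetuximab, and the dim FXYD2 had 21.5 and 22.1. Kidney lineage genes stood at 0.07 over 11, neuronal lineage at -0.05 over 16, keratinocyte markers at 0.04 over 14, fibroblast and matrix genes at 0.04 over 17, cell junction genes at -0.05 over 21 and complement and coagulation at -0.12 over 18.

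A further 526 genes were well above background with cetuximab only, 173 of them at least 2-fold higher, and 1244 in the control only, 43 of them at least 2-fold lower with cetuximab. The largest bounds with cetuximab were those of ATP2A3, a calcium pump of the endoplasmic reticulum (at least 7.72-fold), UBTFL1 (at least 6.47-fold) and MOBP, a myelin protein (at least 6.46-fold). In the control they were those of CNTN4, a neural adhesion molecule, and FAM124A, both at least 4.78-fold, and OPRK1, the kappa opioid receptor, at least 3.58-fold. These genes are dim, and the array with the lower overall signal had fewer genes above background. The lowest well-above-background signal was 15.4 in the control and 14.4 with cetuximab, against 75th percentiles of 232 and 163. After scaling, the floor was thus higher on the cetuximab array, which makes bounds of control-only genes smaller. The 173 and 43 therefore cannot be set against each other, and bounds under other scalings were not examined.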

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

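Among 130 control probes that entered no comparison, other than the E1A spike-ins, 2 were well above background with cetuximab and not in the control. The first belongs to the ERCC set of control sequences, with a median signal of 26.0 intensity units over 35 spots with cetuximab against 4.12 in the control, and 30 of its spots were well above background with cetuximab. The other, an ETG control probe, had a median of 20.7 against 3.55 over 12 spots. Both were singled out as signal in unreported probes above the control array's level. The lowest signal of a non-control probe marked well above background was 14.4 with cetuximab.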

How the results depend on the processing

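Scaling on the detected probes, quantile normalization, loess on signal or on signal and GC, the mean of a gene's probes and kept outlier spots left the 88 higher and 22 lower genes within 1.5 times their number. Other settings did not. The counts were 11 higher and 1 lower with normexp, whose offset compresses dim genes, 44 and 75 with median scaling, 22 and 470 without scaling, and 21 and 498 with spike-in scaling. Spike-in scaling, the GC corrections and the lists of settled symbols were chosen after seeing the data. Without a filter on dim probes they were 3014 and 869, and among the brighter genes alone 3 and 1. At 1.5-fold they were 650 and 241, and at 3-fold 17 and 1. The median of all genes moved from -0.04 to -0.24 with median scaling, -0.55 without scaling, -0.56 with spike-in scaling and 0.15 without the filter, so list medians are compared relative to it. Lists outside the middle 95% of random lists numbered 12, between 8 and 13 under the other settings (10 with matching on GC or without matching, 9 among settled symbols) and 7 with the mean of a gene's probes; the cause was not tested. Among the 12 lists, relative medians changed sign for ribosomal proteins with quantile normalization (-0.016), for MHC class I genes with normexp (-0.049) and without a filter (-0.078), and for immediate early genes without a filter (-0.033); the cause was not tested. Of the 28 lists inside the middle 95%, 20 had relative medians on both sides of 0 over the settings. The relative median of p53 targets lay between 0.0075 and 0.26 and that of ERK output between -0.33 and -0.023. Interferon-stimulated genes kept a relative median between 0.17 and 0.30 and the integrated stress response between -0.39 and -0.17 over 13 settings. Median scaling, detected-probe scaling, no scaling and spike-in scaling shift all genes equally. Relative medians and list percentiles could not change under them, so these settings were no check on the lists. Outlier spots kept left 526 and 1244 genes on 1 array only. The authors' own value table was not run as an alternative, since its columns could not be tied to the samples, and with 1 array per group neither leaving out a replicate nor a slide block could be run. No paired analysis was possible because each group had 1 array. Low signal over background limits the dim genes, where the technical SD reached 0.37.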

Other observations

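Probe GC content carried a small trend of its own. The median difference was -0.09 log2 over 7791 probes under 40% GC and 0.19 over 216 probes of at least 70% GC, and across probes the Spearman correlation with GC was 0.19. Before scaling, the ribosomal RNA probes RN18S1 and RN5-8S1 differed by 0.38 and 0.49 while the median gene differed by -0.55 and the spike-ins by 0.01.

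The comparison of second probes for ERK genes was set before its values were seen, loess on mean signal was an alternative fixed beforehand, and the other tests in this part were chosen after. Interferon-stimulated genes were higher with cetuximab. Removing the trends with mean signal and probe GC left their list at percentile 100 of random lists, which argues against those trends as the whole cause. RNA of keratinocytes, the type of the other cell line named in the labels, stays open, with 14 measured markers at percentile 72.9. The brightest, KRT10, KRT17 and KRT14, were at -0.22, -0.52 and -0.44, and their high levels would hide a small share. Of 31 keratinocyte markers on the array, 0 were well above background with cetuximab only and 1 in the control only, so none newly appeared. RNA of immune cells stays open too, with their markers at percentile 96.4 (97.8 with GC matching). The brightest, CD4, CD79A and CD68, were at 0.14, 0.23 and -0.26. Of 23 immune cell markers on the array, 0 were well above background with cetuximab only and 1 in the control only. Of 28 measured interferon-stimulated genes, 23 were above 0 and 5 below, and the list median lay above all 10000 random lists. Probes of the random lists may hold faults too, so this argues against faults of a few single probes as the source of the list's shift. For single members such faults stay open, because only 4 interferon-stimulated genes had a second probe. A response to cetuximab may be the source, and it stays open and untested, as does a chance difference between the cultures, with 1 array per group.

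ERK pathway output genes were lower, the direction that a block of growth factor signalling may give. The list's median relative to all genes was -0.14 before any trend was removed. It was -0.15 after trends with signal and GC were removed (percentile 1.34) and -0.11 after the signal trend alone (percentile 5.31). Neither removal took the shift away, so these sizes give no support to a trend as the whole cause. With normexp, which compresses dim genes, the relative median was -0.023, so the size of the shift depended on how background was handled. A part played by a trend stays open, since the list lay inside the random range after the signal trend alone was removed. Only 3 members had a second probe, too few to set against random sets. No EGFR probe was well above background on both arrays, and a biological cause was not tested.

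Ribosomal protein genes were higher, and the bright end of the signal scale may be a source. The 18 other genes with settled symbols between the list's signal quartiles had a median of 0.32, above the list's own 0.22. The list stood at percentile 95.9 after loess on mean signal but 97.9 after loess on signal and GC. Its 32 second probes stood at percentile 100 without loess. They may carry the same bright-end trend, so they cannot tell it apart. Unscaled, RPS18, the member with the largest difference, had 198690 intensity units in the control and 199879 with cetuximab. The list's median of 0.22 is smaller in size than the unscaled shift of the 75th percentile (-0.51), so unscaled it lies below 0. With matching on signal and GC the list stood at percentile 100. That matching used fewer signal bins than the main one, whose bins already did not match this list's brightness. It therefore cannot tell a GC trend from the bright-end trend, and a part played by probe GC stays open. A response of ribosomal genes to cetuximab is not excluded.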
